A study of Caenorhabditis elegans with 3 samples.

How the data were processed

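Peak lists from EGL-27 ChIP-seq in 3 biological replicates of whole L1 larvae were analysed as 1 group, taken with the replicate numbers from the labels. Per the labels, chromatin was sheared by sonication with a microtip. The authors listed regions for each replicate and for the 3 replicates together, each against 1 control alignment shared by the replicates, and deposited these relaxed lists (peaks and background, the input to IDR) with 1 thresholded IDR list, on builds ce11 and ce10. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal value of each region is the authors' own measure of its height relative to control, on a scale that is not stated. It was used to describe and rank regions within a list, to correlate replicates across IDR peaks and to compare promoter with other IDR peaks. The deposited −log10 q-value was equal to its maximum, 3.17, in all 524 IDR peaks, so it was not used for ranking. The deposited summit offset gave the position of each peak. The IDR list was exactly the 524 highest regions of the pooled list by signal. The control alignment and signal tracks were not analysed here. Depth per sample is unknown, since the lists hold no read counts, and intervals cover only the counting of peaks or genes.

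All coordinates are on ce11, 1-based, with genes from Ensembl release 115 (WBcel235, the same assembly) and the matching RefSeq sequence; 0 regions ran past a chromosome end. ce10 lists were used only for counts and overlaps within ce10, and no coordinates were converted. A promoter window ran from 1000 bp upstream to 200 bp downstream of the annotated start of each of 19973 protein-coding genes. Each summit had 1 class, in the order promoter, 5' UTR, coding exon, 3' UTR, intron, noncoding gene, intergenic. Classes, top-list overlap, short noncoding RNA genes (within 500 bp) and the egl-27 and unc-119 neighbourhoods (within 20 kb) were tested with 100000 circular shifts within chromosomes (1000 for relaxed regions near egl-27 and unc-119, 10000 for gene list counts), gene lists with Fisher's exact test, chromosome and arm shares with exact binomial tests, motifs with exact McNemar tests in windows of 100 bp either side of the summit, and signal with permutations. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. Intervals are exact 95% binomial intervals.

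Gene lists, motifs, tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule took egl-27 and unc-119, the promoter genes (or the nearest start) of the 20 highest IDR peaks, the 4 members with the highest promoter peaks of each list that passed its test, and every Hox, Wnt and GATA gene with a promoter peak. Sets without a replicate were the IDR peaks in the top lists of both other replicates; IDR was not rerun. Alternatives were other promoter windows, peak sets, these replicate subsets, positions, overlaps, backgrounds, gene assignments, motif windows and the ce10 lists. On 100 simulated sets of 524 random positions, any call was made in 5 sets over 7 classes, 7 sets over 28 gene lists and 7 sets over 15 motifs. These positions were drawn independently and evenly, so they could not show calls that arise from clustered peaks or from the higher GC content of real summits. With 100 peaks placed in promoters, 20 of them at ribosomal protein genes, and GAGAGA placed in 100 windows, the promoter class, that list and that motif were each called in 100 of 100 sets. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.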

Results

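The data were chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for EGL-27 in first-stage (L1) larvae of the nematode Caenorhabditis elegans. EGL-27 is a GATA-type zinc finger protein related to the MTA subunits of the NuRD chromatin complex. The larvae were whole animals of both sexes from a transgenic strain that expresses EGL-27 fused at its C-terminus to GFP and FLAG tags. The labels give 3 biological replicates of 1 group and no second condition, so the comparisons are between bound regions and the genome, and between replicates. The authors' list of peaks that passed their irreproducible discovery rate (IDR) threshold held 524 regions on build ce11, with signal values from 28.9 to 166.1. The longer relaxed lists held 30000 regions in replicate 1, 30000 in replicate 2, 13516 in replicate 3 and 30000 for the 3 replicates together. Read depth is unknown, because the files hold no counts.

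The strongest peaks of each replicate overlapped in part. Of the 524 IDR summits, 57.4% (95% exact interval 53.1 to 61.7) lay in one of the 524 highest regions of replicate 1, 61.8% (57.5 to 66.01) in those of replicate 2 and 66.03% (61.8 to 70.1) in those of replicate 3. Shifted positions gave 0.201%, 0.219% and 0.200% (one-sided circular-shift permutation p = 1e-05 each, the smallest the shifts can give). In all 3 top lists lay 134 summits, with a median pooled signal of 60.1, and in none of them lay 22, with a median of 31.3. Between replicates, 35.3% to 43.3% of the 524 highest regions of one were among those of another. Across IDR peaks, which are not independent replicates, the Spearman correlation of signal was 0.20 between replicates 1 and 2 (491 peaks), 0.29 between 1 and 3 (489 peaks) and 0.27 between 2 and 3 (508 peaks). These peaks are the highest by the signal of the 3 replicates together, a choice that itself shapes the correlations, so they are given as values without a test. The IDR list was made from the same reads as the replicate lists, so overlap above shifted positions is built in.

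EGL-27 peaks lay in promoter windows more often, and in coding exons far less often, than the genome would give. Of the 524 summits, 234 (44.7%, 40.3 to 49.0) lay between 1000 bp upstream and 200 bp downstream of the start of a protein-coding gene, against 20.9% ± 1.83 (SD) of shifted positions. Coding exons held 3 summits (0.573%, 0.118 to 1.66) against 19.6% ± 1.80, and 3' UTRs held 2 against 2.46%. Introns held 115 (21.9%) against 30.9%, and intergenic sequence 141 (26.9%) against 22.1%. The adjusted p was 7e-05 for promoters and coding exons, 9.33e-05 for introns, 0.00098 for 3' UTRs and 0.0256 for intergenic sequence (two-sided circular-shift permutation, Benjamini-Hochberg over 7 classes). 5' UTRs (6 summits, adjusted permutation p = 0.571) and noncoding genes (23 summits, adjusted p = 0.22) did not pass; with promoter windows of 500 bp upstream, noncoding genes held 30 (5.73% against 3.51%) and passed (adjusted permutation p = 0.0269). The 29476 relaxed regions outside the IDR list had 25.4% of summits in promoters and 20.02% in coding exons. The IDR list, made from all 3 replicates, was not called again with fewer; below, without replicate 1 (216 peaks), 2 (200) or 3 (187) means the IDR peaks in the top lists of both other replicates, sets that share 134 peaks. The intron call was lost without replicate 1 (23.6%, adjusted permutation p = 0.0535) or 2 (26.5%, p = 0.291), the intergenic call without replicate 1, 2 or 3 (adjusted permutation p = 0.0535, 0.097 and 0.127), and the 3' UTR call without replicate 2 (0.5%, adjusted permutation p = 0.136), in the 262 peaks of highest signal (0.0513) and in all 3 top lists (0.152).

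**Figure D1:**
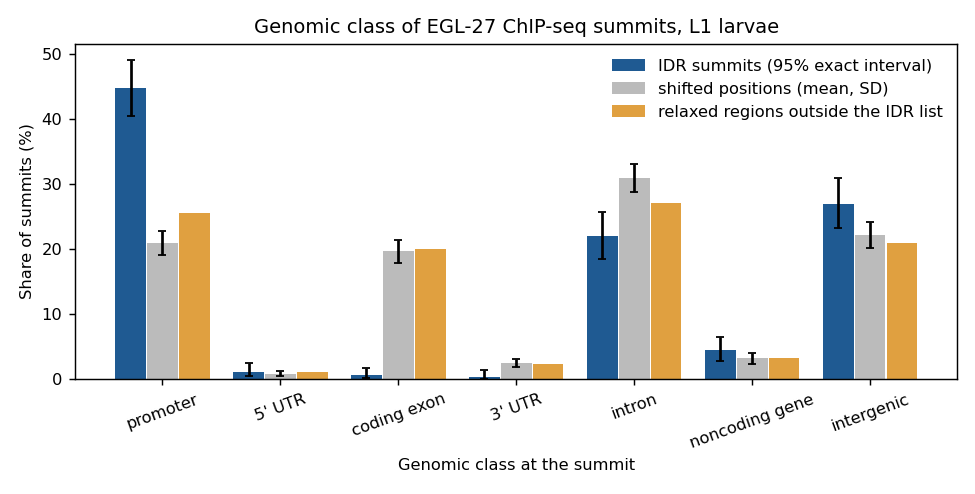
Share of summits (y axis, percent) in each genomic class (x axis) for 524 IDR peaks with 95% exact intervals, shifted positions with SD, and relaxed regions outside the IDR list. Promoters hold 44.7% of IDR summits against 20.9% of shifted positions, and coding exons 0.573% against 19.6%.

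The highest peaks included promoters of cdc-48.1, puf-9 and ribosomal protein genes, and distal sites in introns and between genes. The highest, with a signal of 166.1, lay on chromosome III from 12612589 to 12612760 in an intron, 3377 bp downstream of the start of Y111B2A.12. The next, with a signal of 159.2, lay on III from 7155752 to 7155973 between genes, 2036 bp upstream of ogt-1, which encodes O-GlcNAc transferase. The summit of the peak of rank 3 (signal 129.0, II from 10563493 to 10563654) was 163 bp upstream of cdc-48.1, which encodes an AAA ATPase of the p97 family. The peak of rank 7 (signal 96.8, X from 5841250 to 5841358) was 333 bp upstream of puf-9, a Pumilio-family RNA-binding protein gene. The summit of rank 10 (signal 95.7) lay 287 bp upstream of rpl-20 and 175 bp upstream of Y17G9B.5, and that of rank 12 (signal 92.9) 346 bp upstream of rpl-15 and 468 bp upstream of K11H12.8. Other promoter summits among the 20 highest were at nspc-17 (763 bp upstream), serp-1.1 (293 bp), K12H4.5 (500 bp), and iff-2 (66 bp) with F54C9.14 (869 bp). Distal summits included one 1906 bp downstream of the start of nhr-3, one 1705 bp upstream of egl-9, which encodes the HIF prolyl hydroxylase, and one 2889 bp upstream of sma-9, a zinc finger gene of the BMP-like pathway. For the remaining distal summits the nearest starts were those of F53A3.1 (18298 bp), tbc-6 (5329 bp; rank 9 with a signal of 96.4, in an intron of egl-27), ztf-1 (3498 bp), K02D3.1 (6019 bp), R03E9.2 (4511 bp), W02H3.3 (4017 bp) and nhr-1 (8137 bp). The rank 9 summit belongs to the group around egl-27 described below, which extra copies of the locus in the transgene may account for. Median signal was 37.7 in the 234 promoter peaks and 38.9 in the 290 others, a difference that did not pass (two-sided permutation p = 0.42).

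Among 28 gene lists fixed beforehand, cytoplasmic ribosomal protein genes carried promoter peaks most often. Of 80 such genes 20 had one (25%, 15.99 to 35.9), against 1.48% of other protein-coding genes (odds ratio 22.1, adjusted Fisher's exact p = 2.09e-17). The list's symbol pattern left out rpl-7A (signal 38.3, 96 bp upstream), noticed after its peak was seen; with it 21 of 81 had one (odds ratio 23.3). With the nearest start 13 of 80 had one (odds ratio 8.58), and the odds ratio was 35.6 in the 262 peaks of highest signal, 31.2, 53.8 and 38.4 without replicates 1, 2 and 3, and 54.5 in all 3 top lists. The highest were rpl-20 (signal 95.7), rpl-15 (92.9), rpl-35 (84.5) and rpl-3 (84.3), with summits 271 to 426 bp upstream of the start. Stress response genes had peaks at 5 of 35 (odds ratio 10.6, adjusted Fisher's exact p = 0.00194), among them the HSP70-family genes hsp-3 (54.8) and hsp-1 (47.1), the mitochondrial chaperonin gene hsp-60 (44.1) and the FOXO gene daf-16 (37.5). Vacuolar ATPase genes had peaks at 3 of 20, vha-8 (51.1), vha-12 (49.4) and vha-13 (30.5; odds ratio 11.1, adjusted Fisher's exact p = 0.0254). Chemoreceptor genes had none at 1308 genes, against 1.69% of other genes (adjusted Fisher's exact p = 1.48e-08), an upper 95% limit of 0.282%. Shifted positions, which stay on their chromosome, gave 5.84 chemoreceptor genes (adjusted permutation p = 0.0411), and in all 3 top lists the call was lost (adjusted Fisher's exact p = 0.325). The shifts do not keep places in chromosome arms or centres, which differed in peaks (below), so an effect of where these genes lie was not separated. All Fisher's exact tests of the lists are two-sided, with Benjamini-Hochberg adjustment over the 28 lists. The stress response and vacuolar ATPase calls rested on few genes: without replicate 2, that is among the 200 IDR peaks in the top lists of replicates 1 and 3, 1 stress gene (adjusted Fisher's exact p = 0.752) and 0 vacuolar ATPase genes had one, and without replicate 3 both counts were 0 (adjusted p = 1). The vacuolar ATPase call was also lost with windows of 500 bp (adjusted Fisher's exact p = 0.152) or 2000 bp upstream (0.0641), with the nearest start (0.209) and in the 262 peaks of highest signal (0.0622).

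Lists of developmental regulators did not pass Fisher's exact test against other genes for the share with a promoter peak, while some passed under other planned settings. Hox genes had promoter peaks at 0 of 6, GATA factors at 0 of 11, NuRD and MTA related genes at 0 of 15 (adjusted Fisher's exact p = 1 for each), with upper 95% limits of 45.9%, 28.5% and 21.8%. Shifted positions gave 0.0391, 0.0639 and 0.0853 genes in these lists, so a count of 0 is no sign of avoidance. Summits outside promoter windows are not counted here: egl-27, a member of the last list, held 6 inside the gene. In the Wnt pathway 1 of 28 genes had a promoter peak, the Dishevelled gene mig-5 (signal 64.1, 166 bp upstream, adjusted Fisher's exact p = 0.625). Cell cycle genes had peaks at 3 of 30 (adjusted Fisher's exact p = 0.0645), nuclear hormone receptors at 7 of 269 (adjusted p = 0.483) and histones at 3 of 72 (adjusted p = 0.327). Against shifted positions, which put fewer summits in promoters of any kind, the cell cycle count (0.183 expected) and the nuclear hormone receptor count (1.26 expected) both passed (adjusted permutation p = 0.00896 for each). When each summit was given to the gene with the nearest start, nuclear hormone receptors (16 of 269, adjusted Fisher's exact p = 0.00426), heterochronic and molting genes (4 of 21, p = 0.00805) and insulin and dauer genes (4 of 30, p = 0.0251) passed. That assignment has no fixed window, so the length of sequence around a gene can set its chance of a peak, and no correction was made for it. Detoxification genes had them at 3 of 218 (adjusted Fisher's exact p = 1), muscle genes at 2 of 32 (0.316) and homeobox ceh genes at 2 of 63 (0.564). One gene each had a peak among heterochronic and molting (adjusted Fisher's exact p = 0.568), hypodermis and seam (0.629), insulin and dauer (0.625), basic helix-loop-helix (0.612), proteasome (0.629) and F-box genes (0.273). None had one among intestine, pharynx, neuron and germline genes and hedgehog related genes (adjusted Fisher's exact p = 1 for the first 4 and 0.906 for the last), collagens (0.469), neuropeptides (0.469) and C-type lectins (0.167).

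**Figure D2:**
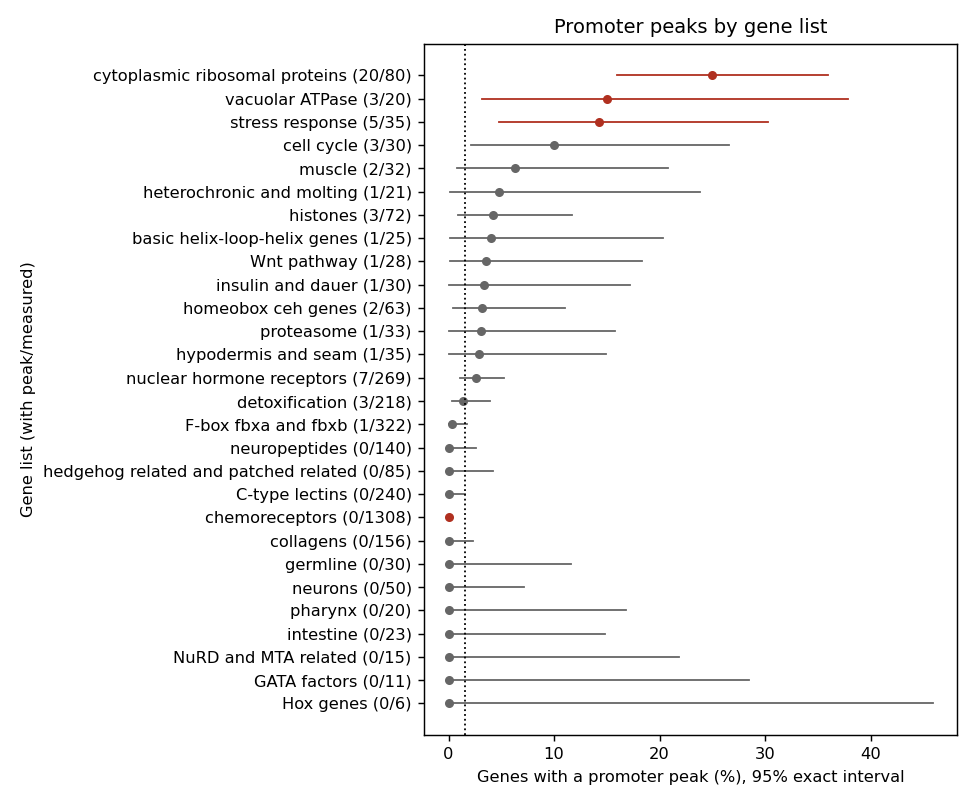
Percent of genes with an IDR summit in the promoter window (x axis) for each of 28 gene lists (y axis), with 95% exact intervals; red marks lists past the test and the dotted line is the share of all protein-coding genes, 1.58%. Cytoplasmic ribosomal protein genes stand at 25% and chemoreceptors at 0.

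EGL-27 summits were rich in GA repeats, and held several AT-rich motifs less often than nearby windows, which were lower in GC content; most of those deficits were absent against shuffled windows of the same composition. GAGAGA lay within 100 bp of 296 of 524 summits (56.5%), against 10.7% of windows 500 bp away (adjusted p = 1.34e-50, two-sided exact McNemar test, Benjamini-Hochberg over 15 motifs). The E-box CACGTG was at 11.3% against 3.05% (adjusted exact p = 1.02e-06) and the GC box CCGCCC at 11.5% against 5.73% (adjusted p = 0.00197). The GATA site WGATAR was less frequent at summits, 32.4% against 39.5% (adjusted exact p = 0.0319), as were TATA-like sites, 10.5% against 27.9% (adjusted p = 3.05e-12), and the homeodomain core TAATTA, 2.10% against 10.1% (adjusted p = 3.02e-07). GC content was 46.98% at summits and 35.8% in the nearby windows. Against dinucleotide-shuffled summit windows, the GATA site was higher at summits by 6.49 percentage points (adjusted exact p = 0.0375), the opposite direction. Each window had 1 shuffled version, so p-values on this background leave out variation between shuffles, which matters most near the threshold. On that background TAATTA and TGATAA differed by -0.382 points each (adjusted exact p = 1), and TATA-like sites were 3.63 points higher without passing (adjusted exact p = 0.0554). GAGAGA (56.5% against 25.8%), the E-box (11.3% against 4.77%) and the GC box (11.5% against 4.01%) stayed higher. Of the other motifs, TGATAA, SKN-1, heat shock, TCF and splice-like sites were less frequent at summits than in nearby windows (adjusted exact p of at most 0.00754), but against shuffled windows the SKN-1 (adjusted exact p = 1) and heat shock (0.0532) differences did not pass, while TCF (-5.15 points, 0.0249) and splice-like sites (-11.3 points, 0.00026) stayed lower. With windows of 50 bp either side the heat shock difference was -0.573 points (adjusted exact p = 0.772). DAF-16 (0.696), PHA-4 (0.21), nuclear receptor (0.744) and EGR-like sites (1) did not pass against nearby windows, yet against shuffled windows PHA-4 sites were higher, 42.2% against 24.6% (adjusted exact p = 8.95e-09), as were DAF-16 sites, 5.15% against 2.10% (0.0226). In the smaller sets without replicate 1, 2 or 3, the E-box (4.63 to 6.50 points, adjusted exact p = 0.0631 to 0.165) and GATA differences (-2.31 to -6 points, 0.275 to 0.758) no longer passed. Nor did those of the GC box (5.35 to 6.02 points, adjusted exact p = 0.0631 to 0.148), TCF (-6.94 to -7, 0.0593 to 0.11) and heat shock sites (-4.63 to -5.50, 0.0799 to 0.165), which were about as large as in all 524 peaks (5.73, -5.73 and -5.92 points). TGATAA did not pass without replicate 1 (-3.70 points, adjusted exact p = 0.364) or 2 (-8, 0.0566), against -12.02 points in all peaks. In the 134 peaks of all 3 top lists the differences were smaller for the E-box (2.99 points against 8.21, adjusted exact p = 0.581), GATA (-1.49, 0.962), TGATAA (-5.22, 0.361) and heat shock (-2.99, 0.53), and TAATTA (-6.72, 0.177), TCF (-8.21, 0.177) and the GC box (5.97, 0.215) did not pass either. GATA (adjusted exact p = 0.0775) and the GC box (0.0705) also missed the threshold in the 262 peaks of highest signal, and GATA without peaks near short noncoding RNA genes (0.0788).

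**Figure D3:**
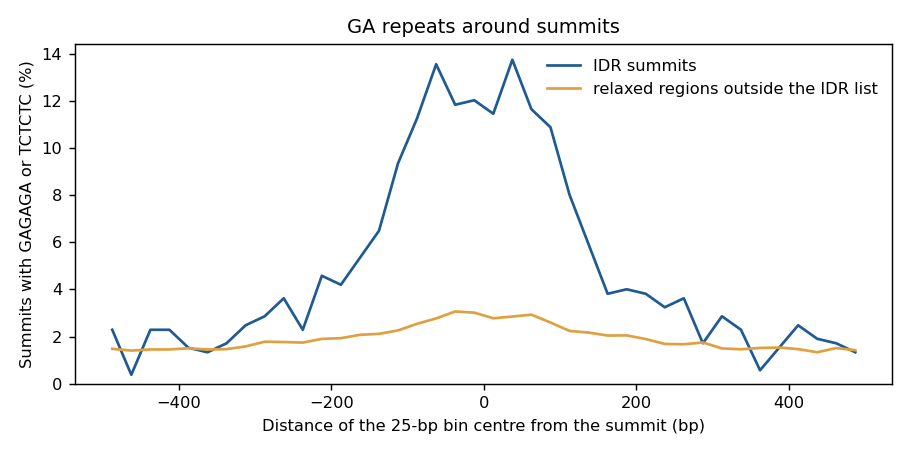
Percent of summits (y axis) with GAGAGA on either strand starting in each 25-bp bin, by distance from the summit in bp (x axis), for IDR peaks and for relaxed regions outside the IDR list. Within 100 bp, 56.5% of IDR summits and 17.3% of relaxed regions hold the repeat.

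The X chromosome held more peaks, and chromosomes IV and V and autosome arms fewer, than their length would give. X held 133 of 524 peaks (25.4%, 21.7 to 29.3) against 17.7% of the genome (p = 9.56e-06, adjusted p = 2.87e-05) and 13.7% of protein-coding genes (p = 1.22e-12, adjusted p = 3.67e-12; two-sided exact binomial tests, Benjamini-Hochberg over 6 chromosomes). V held 64 (12.2%) against 20.9% (exact binomial p = 2.86e-07, adjusted p = 1.72e-06). IV held 71 (13.5%) against 17.4% of length (exact binomial p = 0.0182, adjusted p = 0.0363), but did not pass against its 16.43% of genes (adjusted p = 0.115). I, II and III did not pass against length (adjusted exact p = 0.669, 0.269 and 0.192). The arms of the autosomes, the outer 0.25 of the length at each end, held 123 of 391 peaks (31.5%, 26.9 to 36.3) against 50% of length (exact binomial p = 1.74e-13) and 44.3% of autosomal genes (p = 2.36e-07). Relaxed regions outside the IDR list lay on X at 20.99% (Fisher's exact p = 0.0173 against the IDR share) and in arms at 41.997%. Inside promoter windows 20.5% of summits were on X, against 14.5% of promoter sequence (exact binomial p = 0.0119), and outside them 29.3% against 18.5% of the other sequence (p = 9.82e-06). These binomial tests count each peak as independent, although some peaks lie in groups, as around egl-27. Their p-values may therefore be too small, which matters most for the call on IV.

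Summits near short noncoding RNA genes were more frequent than shifted positions. Of the 524, 40 (7.63%, 5.51 to 10.2) lay within 500 bp of a tRNA, snRNA, snoRNA or rRNA gene, against 1.15% of shifted positions (permutation p = 2e-05, the smallest the shifts can give). They included 20 near snoRNA, 13 near tRNA and 7 near snRNA genes, and 0 near rRNA genes. Of the 19 promoter peaks of ribosomal protein genes, 2 were among these 40.

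A dense group of peaks lay in and around the tagged gene, a group that extra copies of the locus in the transgene may account for. Within 20 kb of egl-27 (WBGene00001194, II from 6835008 to 6847908, plus strand) lay 15 IDR summits against 0.31 for shifted positions (two-sided permutation p = 0.0026), 6 of them inside the gene. Only 1 of the 15 lay in a promoter window, that of tbc-6, and 0 in that of egl-27. The relaxed lists of replicates 1, 2 and 3 had 53, 53 and 50 regions there, 3.36, 3.21 and 6.78 times the shifted mean. The strain's unc-119 gene (WBGene00006843, III from 10902641 to 10908935), which is mutated in the parent strain and serves as a rescue marker, had 0 IDR summits within 20 kb against 0.284 (permutation p = 1), a number at which no difference was detectable.

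**Figure D4:**
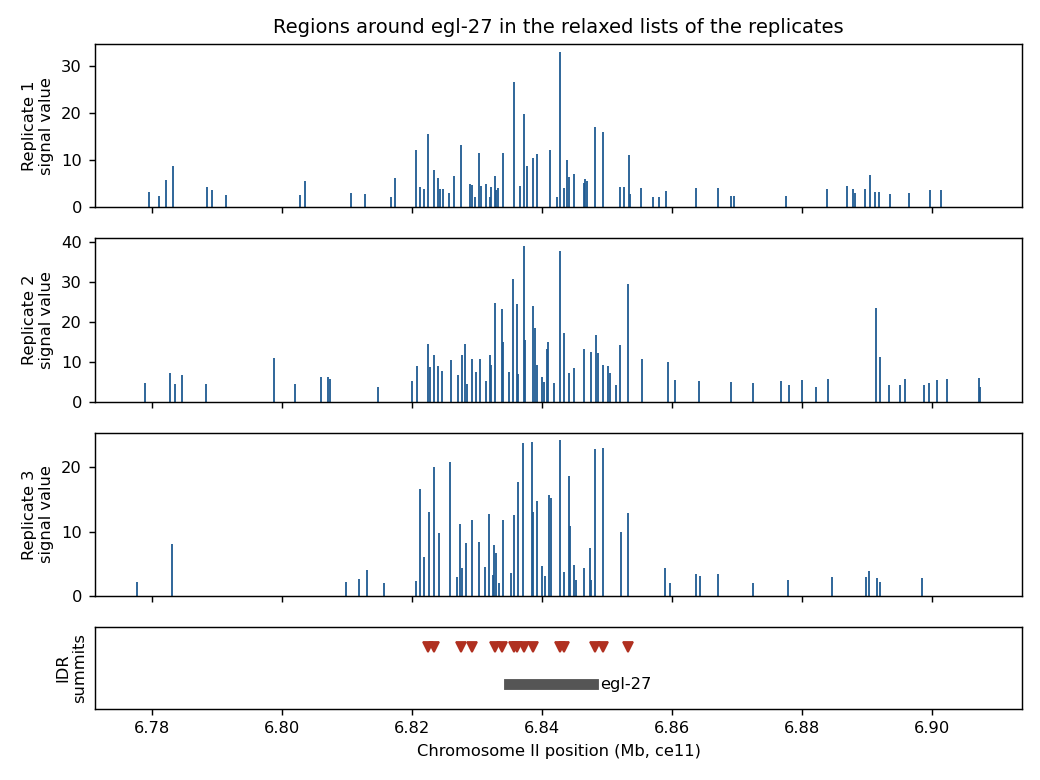
Signal value (y axis) at the summits of relaxed-list regions of replicates 1, 2 and 3 by position on chromosome II in Mb (x axis), with the 15 IDR summits within 20 kb of egl-27 and the gene below. Between the first and last of the 15 summits the replicates have 39, 46 and 41 regions, and 7 to 12 in each stretch of the same length beside it.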

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

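The sets without the egl-27 neighbourhood or without peaks near short noncoding RNA genes, the ribosomal protein list with rpl-7A, and the comparison of the X share with relaxed regions, were chosen after seeing the data. The promoter share (35.1% to 57.3%), coding exon scarcity, X share (25.4% to 31.3%), arm share, top-list overlaps, short RNA share and egl-27 count kept their direction and side of the threshold under every alternative that was tested. On ce10 the top-list overlaps (57.1%, 61.7% and 65.8%), X share (25.6%) and peak number (559) are values with no test. Replicate correlations ran from 0.16 to 0.32 with Pearson's measure, ce10 lists or the upper set. Stricter peak sets hold fewer peaks (262 in the upper set by signal, 134 in all 3 top lists, 187 to 216 IDR peaks in the top lists of both replicates other than 1, 2 or 3, named without a replicate here although the list was made from all 3), which by itself can lower the number of calls. Of 7 classes, 5 passed in the full list, 2 in the upper set, 2 in peaks in all 3 top lists, 2 to 4 without a replicate, 4 with 2000 bp windows and 6, noncoding genes gained, with 500 bp windows. The intron share was 24.4% in the upper set and 23.9% in all 3 top lists, and 21.9% to 26.5% without a replicate. The intergenic share was 27.5%, 29.1% and 28.3% to 29.2% in those sets, and 18.5% with 2000 bp upstream windows; all of these no longer passed, except introns without replicate 3. Of 28 gene lists, 4 passed in the full list, 1 in all 3 top lists, 2 to 4 without a replicate, 6 with either the nearest start or the circular shift, and 3 in the upper set or with either other promoter window. Odds ratios for stress response and vacuolar ATPase genes were 0 in all 3 top lists; without a replicate they ran from 0 to 17.1 and from 0 to 20.04. That for cell cycle genes was 0 in the upper set, in all 3 top lists and without each replicate, while by circular shift their count was 16.39 times the shifted mean and passed (adjusted permutation p = 0.00896). Of 15 motifs, 11 passed in the full list, 4 in all 3 top lists and 5 to 6 without a replicate, and 8 against shuffled windows, with PHA-4 and DAF-16 gained and TGATAA, SKN-1, heat shock, TATA and homeobox lost. Against dinucleotide-shuffled windows the GATA difference turned to 6.49 points and the TATA difference to 3.63 points; that background keeps the composition of the summit. The signal difference between promoter and other peaks was 0.134 in all 3 top lists and -0.0727 to 2.45 without a replicate, and passed in none; the cause was not tested. The planned set of peaks above an IDR score minimum was not run, because the score column is 0 in every IDR peak. Unknown read depth limits every statement about absent peaks.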

Other observations

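Tests of promoter binding at egl-27, of gene bodies, of the caller, and of the 6-mer, as well as the test of extra transgene copies, were chosen after the results were seen; both GC tests were set before theirs.

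Several long genes held more than 1 IDR summit; they were picked after their values were seen. After egl-27 with 6, zfp-1, which encodes a PHD finger and AF10-related chromatin protein, had 5 over 14.8 kb, ccch-1 had 4 over 13.4 kb and pqn-41 had 4 over 33.6 kb. Of all IDR summits 33.8% lay over 2 kb from the nearest protein-coding start. GAGAGA was at 62.1% of summits outside promoters and 49.6% inside them (Fisher's exact p = 0.00459), and at 22.5% of the 40 summits near short noncoding RNA genes. The 209 relaxed regions that tied for the highest q outside the IDR list resembled it in class, with 48.3% in promoters (41.4 to 55.3), 1 in a coding exon and GAGAGA at 52.6%, while 3 ribosomal protein genes had one in the promoter (adjusted Fisher's exact p = 0.211).

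The 15 IDR summits around egl-27 spanned 30737 bp, with regions in this span at 39, 46 and 41 in replicates 1, 2 and 3 and 7 to 12 in each stretch of the same length beside it. A count at the promoter of egl-27 could not decide on the group as a whole, because most summits spread over such a span cannot fall in a single promoter window. It shows only where the summits lay: 0 of the 15 were in the window of the gene's own annotated start (0%, upper 95% limit 21.8%), and 1 with 2000 bp upstream (6.67%, upper limit 31.9%). Extra copies of the locus in the transgene may account for the group: relaxed regions outside the IDR list were 2.32 times as dense there as shifted positions (permutation p = 0.002, the smallest that 1000 shifts can give). However, GAGAGA was at 66.7% of the 15 summits and 56.2% of the others (Fisher's exact p = 0.599), where the prediction was a lower share. That prediction was a weak one, because copies of bound sites would keep the motif, so copies and binding within the locus cannot be told apart here.

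Promoter peaks at ribosomal protein genes were weighed against 2 technical explanations. GC content of the whole promoter window is argued against as the whole cause: the odds ratio stratified by it was 14.8 (95% interval 8.66 to 25.3), against 22.1 unstratified. Window GC was 37.2% for these genes and 35.2% for all, and GC content local to their summits was not tested. For signal spread over strongly transcribed gene bodies, summits inside the genes were counted. There were 0 in the 63.2 kb inside these genes and 19 in the 75.6 kb of the 1000 bp upstream. Coding exons of all genes held only 3 of the 524 summits, so their absence inside these genes is not particular to them. The count therefore shows where the summits lay and cannot decide on signal spread. Nor is signal spread excluded by the bound set for it: the ratio of rates was 0, but its upper limit, 0.256, just exceeded 0.25. That bound was set after the results were seen. The excess of summits near short noncoding RNA genes, which are also strongly transcribed, leaves a part for transcription possible, although without those peaks the odds ratio was 20.6. No biological explanation was tested, since the design has 1 group.

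The scarcity of summits in coding exons was weighed against base composition and the caller. Random positions matched to the summits in GC content lay in coding exons at 37.1% and in promoters at 18.8%, so GC content argues in the opposite direction from the 0.573% observed. The caller did list coding exons, at 20.02% of relaxed regions outside the IDR list, far above the upper limit of 1.66% for IDR summits. That list includes background, so its share shows that exons were not left out, but not how they scored against the control. Of the 209 relaxed regions at the highest q, 1 was in a coding exon. Open chromatin at promoters was not tested, and the design gives no biological contrast.

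A hypothesis is that a second sequence element apart from GA repeats marks these sites; the tests leave it open. Among 2080 6-mers compared on chromosomes I, III and V, with the 15 summits around egl-27 left out of all 6-mer counts, the most enriched one without GAGA or AGAG in it was ACGCAG, at 37.4% of summits against 4.78% of nearby windows. Of all 2080, CGTCTC, which reads GAGACG on the other strand, had the smallest p. It was only at the summit in 95 pairs of windows and only nearby in 4. GAGACG and other enriched 6-mers, AGAGAC, AGACGC, GACGCA, CGCAGA and CAGAGA, overlap ACGCAG and reach into GA sequence on both sides. On II, IV and X, ACGCAG was at 23.9% of summits against 5.13% in 117 pairs of windows without GAGAGA (exact McNemar p = 0.000195), which does not separate it from shorter GA sequence. On these chromosomes, copies of ACGCAG with no GAGA or AGAG in the 6-mer or the 4 bases on either side were at 13.3% of 279 summits against 3.94% (exact McNemar p = 0.000106). Copies beside such sequence were 64 of 105 at summits and 5 of 16 nearby (Fisher's exact p = 0.0316). On I, III and V they were 67 of 98 and 5 of 13 (Fisher's exact p = 0.0596). Both tests count copies as independent, although on II, IV and X the 105 copies lay in 85 summit windows. From these counts, an element apart and a longer one that includes GA sequence cannot be told apart. The 6-mer had been seen on all chromosomes before this split, so II, IV and X are not an independent test. All 6-mer counts were set against nearby windows, which were lower in GC content than summits, and not against shuffled windows. The element may be a shared feature of open regions; no other factor was analysed here.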
